A study of Mus musculus with 15 samples.

How the data were processed

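The series holds 15 Affymetrix Mouse Gene 2.0 arrays of mouse LSK cells, with 5 arrays in each of 3 groups named by the sample titles: non-cultured, cultured for 18 h without extracellular vesicles, and cultured for 18 h with vesicles of AFT cells. Per the labels' protocols, cells were kept in MyeloCult M5300 medium and biotinylated targets were prepared from 500 pg of total RNA. The series design text calls the 5 samples of a group biological replicates. No batch, date or animal is given in the labels, so batches could not be examined.

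The values are those of the series' deposited table, with 41345 probe sets and 15 columns. The deposited values are on a log2 scale by their range (1.40 to 13.0), although the base is not stated in the sources used here. MAS5 is the only tool in the submitters' processing notes, with no role or version, and the background correction and normalization behind the values are not given in the sources used here. Array medians lay between 4.62 and 4.74, within the limit of 0.5 set in advance, and the values were used as deposited. No signal over background is given, so dim genes could not be told from background. No pair among the 105 pairs of arrays held identical values.

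Gene names came from the platform annotation given with the table. It lists 25335 probe sets, of which 23521 have 1 gene symbol and 1814 several, and 16010 probe sets are unnamed here. Entrez identifiers of 23328 probe sets were found in the RefSeq table of assembly GRCm38.p6, and 0 symbols differed. Probe sets with several symbols or none entered no gene. For the 1082 genes with several probe sets, the one with the highest mean over all 15 arrays was used, which left 22180 genes. Some genes of the fixed lists, and some genes fixed by name, had no probe set of their own and were not analysed here, so 696 of 776 list genes were measured.

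A group-means model was fitted to all 15 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 12 residual degrees of freedom and 3.66 prior ones. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes in each comparison, two-sided, with no minimum fold. Printed standard errors are the moderated ones of the log2 fold change, also where a fold is given. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over 72 tests (24 lists in 3 comparisons), and again with the correlation estimated for each list. Of the called lists, 1 of 7 held with an estimated correlation for EV against without EV, 14 of 16 for without EV against non-cultured and 13 of 16 for with EV against non-cultured.

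The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The lists covered stem cell, myeloid, erythroid and megakaryocyte, lymphoid, and stromal genes, DNA replication, mitosis, cell cycle inhibitors, pro-apoptotic, anti-apoptotic and p53 target genes, immediate early, heat shock, integrated stress, NRF2, interferon and NF-kB genes, sterol synthesis, glycolysis, oxidative phosphorylation, MYC targets, ribosomal proteins, autophagy, and cytokine receptors. By the rule, the text could name per comparison the 10 called genes with the largest rise and the 10 with the largest fall, if at least 20 of the 25 pairs of arrays held the sign. With fewer than 5 called in a direction, it could name the 5 with the smallest p. Up to 4 members of each list with the smallest adjusted p could also be named, as could Kit, Dlk1, Bcl2, Mcl1, Cdkn1a, Myc, Mki67 and a few others in every comparison. Predicted genes, small RNAs and receptor segments were counted but not named, except Snora75, 1 of the 4 genes that fell with EV, which was named after its value was seen.

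The culture score took its genes from the mean of both cultured groups against non-cultured cells, a contrast whose chance error is independent of that of EV against without EV if the groups vary alike. The mean variance per gene was 0.0891 with EV, 0.0708 without EV and 0.0684 in non-cultured cells. The score was compared by a two-sided exact permutation test. Gene counts were compared with those of 100 splits of the 10 arrays of a comparison, the real split included. Medians of lists were given 95% bootstrap intervals over genes, and single arrays far from their group were sought with the Dixon test at 5%. A few alternatives and 1 test were added after the data were examined and are named as such where they are printed. The fits were tested on simulated data for the comparison of EV against without EV over 22180 genes, with 50 genes changed at each of 4 sizes: 48% of genes changed by log2 0.5 were recovered, 92% at log2 1, and 100% at 2 and at 3. Of 181 genes called there, 11 (6.08%) had not been changed. The simulated genes were independent and had no array effects, and more were called than the 44 in the data. Recovery in the real comparison may therefore be lower.

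Alternatives were quantile normalization, median centring, leaving out the dimmest 40% of genes, the mean of a gene's probe sets, all probe sets, a trended and robust prior, only the 2 groups compared, the replicate number as a block, array weights, leaving out each array in turn, a fold of at least 1.5, 50 genes each way in the score, and an estimated correlation between genes. An offset before log2 was planned for linear values and did not apply.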

Results

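Gene expression was measured in mouse LSK cells, a sorted population of hematopoietic stem and progenitor cells, in 3 groups of 5 biological replicates. The cells were taken straight after sorting (non-cultured), after 18 h in culture without extracellular vesicles (EV), or after 18 h with EV released by AFT cells, a stromal cell line. Each sample was hybridised to 1 Affymetrix Mouse Gene 2.0 array, and 22180 genes were compared on the log2 scale. The median log2 signal per array lay between 4.62 and 4.74. The number of arrays sets the precision, and the median standard error (SE) of a fold change between groups of 5 was 0.13 on the log2 scale. Culture was the largest source of variation. The first principal component held 38.2% of the variance and set all 10 cultured arrays apart from the 5 non-cultured ones. The second held 10.7% and was led by the array with EV of replicate 1, whose mean correlation with its group was 0.964 against 0.974 to 0.976 for the other 4. Mean correlation between arrays was 0.973 within the group with EV, 0.979 within the group without EV and 0.980 within the non-cultured group.

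**Figure D1:**
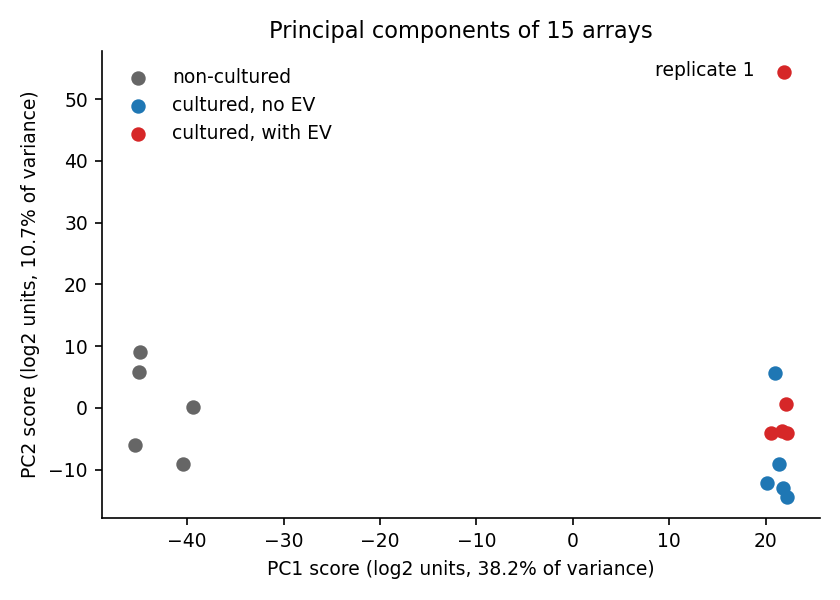
Principal component scores of the 15 arrays over 22180 genes, in log2 units, with 1 point per array coloured by group. The cultured and non-cultured arrays separate along the first component (38.2% of variance), and the array with EV of replicate 1 lies apart at 54.4 on the second.

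The first comparison, with EV against without EV after 18 h, asks what the vesicles change in cultured cells. A small set of genes was markedly higher with EV. Kif1c, a kinesin motor, rose 24.5-fold (log2 4.62, SE 0.24, n = 5 per group, limma adjusted p = 5.74e-08), from a mean log2 signal of 5.12 to 9.74. Wasf3, an actin regulator of the WAVE family, rose 12.6-fold (log2 3.65, SE 0.20), and Cgnl1, which encodes a cell junction protein, rose 7.92-fold (log2 2.99, SE 0.20). Smaller rises were found for Uaca (5.84-fold, SE 0.16 on the log2 scale), Scd1, the stearoyl-CoA desaturase (5.53-fold, SE 0.30), and Ddr2, a collagen receptor (4.96-fold, SE 0.19). Trak2, an adaptor in mitochondrial transport, rose 4.92-fold (SE 0.18), and the cytochrome b5 reductase Cyb5r3 rose 4.55-fold (SE 0.22).

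Among the 22180 genes, 40 rose and 4 fell with EV (limma, Benjamini-Hochberg adjusted p under 0.05), and 1513 had an unadjusted p under 0.05. Of the 40 that rose, 26 did so more than 2-fold, and all 40 were higher in each of the 25 pairs of arrays. By the same test, in culture without EV against non-cultured cells 33 of the 40 were not called, 6 were called lower and 1 higher. With EV, 36 of the 40 were also called higher than in non-cultured cells. Each of these comparisons shares 5 arrays with the one that chose the 40 genes. H2-Q10, a class I histocompatibility gene, rose 7.84-fold (log2 2.97, SE 0.32) on its brighter probe set, whereas its dimmer probe set differed by log2 0.12 (limma adjusted p = 0.907 among all probe sets).

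The genes that fell were Cpox, an enzyme of heme synthesis (log2 -0.98, SE 0.17, limma adjusted p = 0.021), Polr3g, a subunit of RNA polymerase III (log2 -0.78, SE 0.15, adjusted p = 0.0441), the ERK phosphatase Dusp6 (log2 -0.62, SE 0.12, adjusted p = 0.0447) and the small nucleolar RNA gene Snora75 (log2 -1.49), which was chosen after its value was seen. The second probe set of Dusp6 differed by log2 0.01. The next genes in this direction, Immp1l (log2 -0.63, adjusted p = 0.0531) and Oxld1 (log2 -0.55, adjusted p = 0.0805), did not pass. In 15 fits that each left out 1 array, 29 of the 40 higher genes kept their call every time, while Cpox was called in 9, Polr3g in 4, Snora75 in 4 and Dusp6 in 2. Without replicate 2 of the group without EV 29 genes were called, all of them higher, and with the spread taken from the 2 groups alone 32 were called, also all higher.

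**Figure D2:**
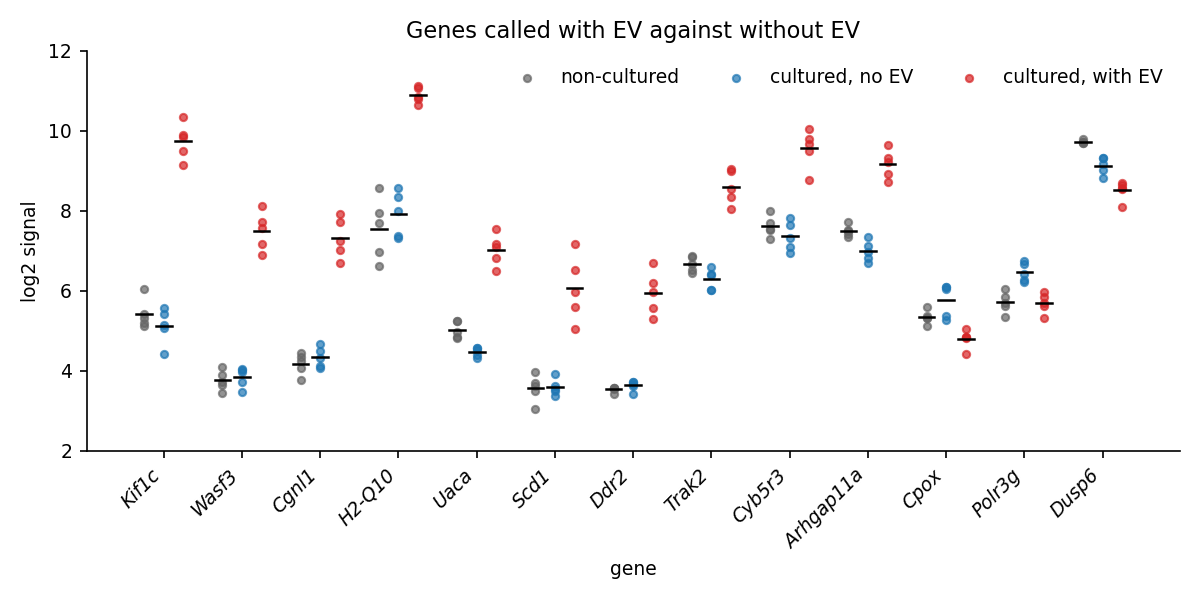
Log2 signal per array of the genes with the largest called rise or fall with EV against without EV, with 5 points per group and a bar at each group mean. Kif1c has a mean of 9.74 with EV and 5.12 without, and each of the 10 rising genes is higher in every array with EV than in every array without.

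Fixed gene lists moved little with EV. Of the 34 measured stromal and mesenchymal genes, Cald1, which encodes the actin-binding protein caldesmon, rose (log2 0.68, SE 0.09, limma adjusted p = 0.00128), and 3 rose when adjusted over the list alone. Other stromal members did not pass over all genes: Ptn differed by log2 0.78 (SE 0.26), the chemokine Cxcl12 by 0.50 (SE 0.13), the matrix protein Sparc by 0.38 (SE 0.11) and Dlk1 by 0.22 (SE 0.13). The list as a whole ranked higher with EV (median log2 0.08, camera adjusted p = 0.00203), a call that was lost at adjusted p = 0.162 with an estimated correlation. Of 33 mitosis genes, Anln, which encodes the cytokinesis protein anillin, rose 2.63-fold (SE 0.20, limma adjusted p = 0.0034), and 3 rose when adjusted over the list alone. Nek2 (log2 0.56), Cenpf (0.65) and Cdc20 (0.55) did not pass over all genes. The mitosis list ranked higher (camera adjusted p = 0.03), with adjusted p = 0.232 with an estimated correlation, and was called in 9 of the 15 fits that left out 1 array.

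The 28 pro-apoptotic genes ranked lower with EV (median log2 -0.10, camera adjusted p = 0.0132, and adjusted p = 0.0268 with an estimated correlation). No single member passed, with 0 called over all genes by limma and 0 adjusted over the list alone. The death-associated kinase Dapk1 differed by log2 -0.56 (SE 0.18), Casp2 by -0.44 (SE 0.18), Htra2 by -0.44 (SE 0.19) and Bik by 0.21 (SE 0.11). This list's call was lost after quantile normalization (adjusted p = 0.0807), without the dimmest 40% of genes (adjusted p = 0.135) and without replicate 3 of the group without EV (adjusted p = 0.109). The stem cell and early progenitor genes also ranked lower (median log2 -0.11, camera adjusted p = 0.00717, and adjusted p = 0.221 with an estimated correlation), with 0 of 35 called and 0 adjusted over the list alone. This call was also lost without replicate 1 of the group with EV (adjusted p = 0.13), after quantile normalization (adjusted p = 0.0515) and without the dimmest 40% of genes (adjusted p = 0.0739). Among them Esam differed by log2 -0.34 (SE 0.11), Mllt3 by -0.36 (SE 0.16) and Prdm16 by 0.47 (SE 0.21).

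Lists of oxidative phosphorylation genes (median log2 -0.06, camera adjusted p = 0.00697), autophagy and FOXO genes (-0.08, adjusted p = 0.0328) and ribosomal protein genes (-0.05, adjusted p = 0.0341) ranked slightly lower, with no member called over all genes or adjusted over the list alone. These gave adjusted p = 0.258, adjusted p = 0.16 and adjusted p = 0.295 with an estimated correlation, in that order, and all 3 calls were also lost after quantile normalization and without the dimmest 40% of genes. The other 17 lists were not called. In 4 of these, DNA replication, integrated stress, anti-apoptotic and p53 target genes, the median, the mean and the test did not share a sign. Dusp6 was the only other list member that passed over all genes, and 1 cytokine receptor or adhesion gene, S1pr1 (log2 -0.50, SE 0.13, limma adjusted p = 0.308), was lower when adjusted over its list alone. Survival and cycling genes fixed by name in advance did not pass: Bcl2 differed by log2 -0.23, Mcl1 by -0.15, Kit by -0.14, Myc by -0.09, Cdkn1a by 0.10 and Mki67 by 0.21. These few genes do not stand for all cell cycle genes, since Anln of the mitosis list rose.

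**Figure D3:**
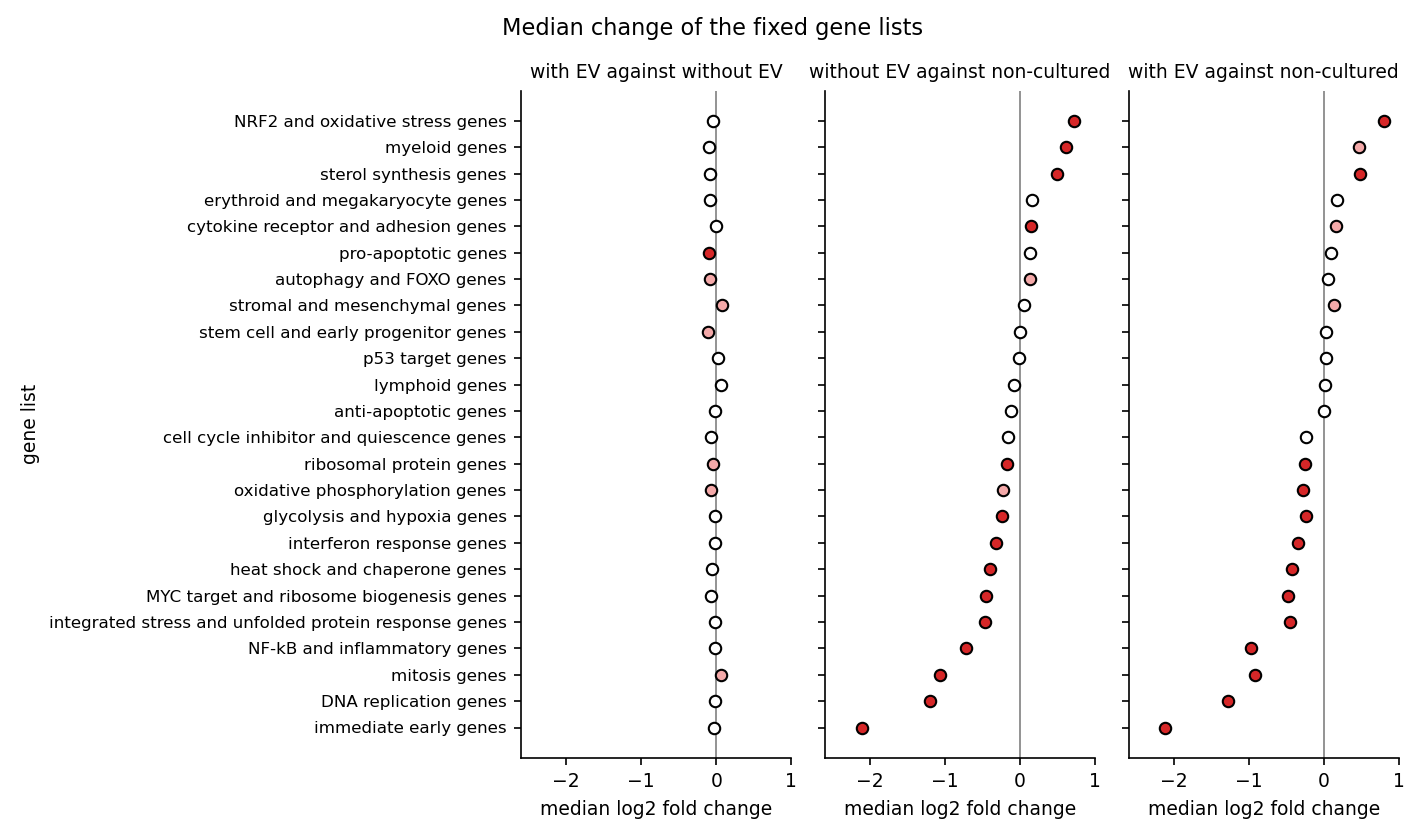
Median log2 fold change of the measured members of 24 fixed gene lists in each of 3 comparisons, with 1 point per list. Dark points passed camera with a preset and with an estimated correlation between genes, pale points with the preset one alone, and open points passed neither. The immediate early genes lie at -2.11 in both comparisons with non-cultured cells and near 0 in the comparison of the cultured groups.

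The second comparison, without EV against non-cultured, asks what 18 h of culture alone changes. Immediate early genes, which respond to stimulation within minutes, were far lower after culture: Nr4a1 fell 42.0-fold (log2 -5.39, SE 0.11, n = 5 per group, limma adjusted p = 2.96e-14), Fosb fell 22.4-fold (SE 0.14), Egr1 18.8-fold (SE 0.21), Nr4a3 18.5-fold (SE 0.20), Nr4a2 17.3-fold (SE 0.14), Fos 13.0-fold (SE 0.26), Jun 12.6-fold (SE 0.25) and Ier2 8.20-fold (SE 0.13). Of 31 measured members 29 fell and none rose, with 30 lower when adjusted over the list alone (median log2 -2.11, camera adjusted p = 7.59e-47). Genes for oxidative stress defence and myeloid function rose. The heme oxygenase Hmox1 rose 38.1-fold (log2 5.25, SE 0.23), the macrophage chitinase-like gene Chil3 38.4-fold (log2 5.26, SE 0.29) and the neutrophil collagenase Mmp8 by log2 4.33 (SE 0.23).

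In total 1497 genes rose and 1525 fell (limma, adjusted p under 0.05), and 1650 and 1399 after quantile normalization. Other large rises were those of Fn1, fibronectin (18.8-fold, SE 0.25 on the log2 scale), Pdk4, a kinase that restrains pyruvate oxidation (18.0-fold, SE 0.23), Chad (14.0-fold, SE 0.22), the integrin subunit Itgb3 (13.0-fold, SE 0.19), Olfr1033 (10.8-fold, SE 0.24) and Mterf1b (13.9-fold, SE 0.85), which varied widely in non-cultured cells (SD 2.14) and was not called with only non-cultured replicates 4 and 5 as the reference (log2 2.45, adjusted p = 0.11). Fn1 belongs to the stromal and mesenchymal list, which as a whole was not called (camera adjusted p = 0.351, with 2 of 34 higher and 1 lower, and the same counts adjusted over the list alone). Among genes that could be named, the largest falls beside the immediate early genes were those of Ptgs2, the inducible cyclooxygenase (31.6-fold, SE 0.29), the kinase Plk2 (19.7-fold, SE 0.17) and Dntt, the terminal transferase of lymphoid progenitors (12.1-fold, SE 0.25).

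Genes of the cell cycle fell. Among 33 DNA replication genes 28 fell and none rose (median log2 -1.20, camera adjusted p = 3.59e-33), and 30 were lower when adjusted over the list alone. Dtl fell 8.04-fold (log2 -3.01, SE 0.17), the helicase subunit Mcm2 3.24-fold (SE 0.10), Mcm3 2.96-fold (SE 0.13) and the clamp Pcna 2.52-fold (SE 0.11). Among 33 mitosis genes 27 fell and none rose (median log2 -1.06, camera adjusted p = 8.58e-24, 28 lower when adjusted over the list alone), including Top2a (3.44-fold, SE 0.14), Bub1 (3.28-fold, SE 0.18), Kif11 (3.24-fold, SE 0.17), Aurkb (2.44-fold, SE 0.15) and Mki67 (2.30-fold, SE 0.15). Cdkn1a, which encodes the cell cycle inhibitor p21, also fell (log2 -1.41, SE 0.16), as did Klf4 (log2 -2.53, SE 0.26), while Tsc22d3 (log2 1.76, SE 0.11) and Txnip (log2 1.28, SE 0.10) rose. The cell cycle inhibitor and quiescence list was not called (camera adjusted p = 0.0945, with 5 higher and 9 lower of 27, and 6 and 9 adjusted over the list alone).

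Genes of ribosome production and protein folding were lower. Of 41 MYC target and ribosome biogenesis genes 21 fell and none rose (28 and 1 adjusted over the list alone, median log2 -0.45, camera adjusted p = 5.24e-13). Those that fell included the ornithine decarboxylase Odc1 (3.07-fold, SE 0.13), Nop58 (2.27-fold, SE 0.11), Ddx21 (2.13-fold, SE 0.14) and Mybbp1a (1.64-fold, SE 0.08). Myc itself did not pass (log2 0.36, SE 0.20, limma adjusted p = 0.301). Of 38 integrated stress and unfolded protein response genes 19 fell and 1 rose (21 and 4 adjusted over the list alone, camera adjusted p = 1.34e-09), including Atf3 (10.7-fold, SE 0.35), Phgdh (log2 -1.85, SE 0.21), Ppp1r15a (3.12-fold, SE 0.16) and the chaperone Hspa5 (2.04-fold, SE 0.10). Of 20 heat shock and chaperone genes 12 fell (14 adjusted over the list alone, camera adjusted p = 1.5e-08), with Hspa9 1.69-fold (SE 0.10) and Hsp90aa1 1.51-fold (SE 0.09) lower. Of 41 ribosomal protein genes 10 fell (13 adjusted over the list alone, camera adjusted p = 7.2e-07), for example Rplp0 (log2 -0.91, SE 0.19) and Rpsa (log2 -0.46, SE 0.09).

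Inflammatory genes were lower on balance. Of 31 NF-kB and inflammatory genes 17 fell and 3 rose (18 and 3 adjusted over the list alone, median log2 -0.71, camera adjusted p = 2.29e-12), including the activation marker Cd69 (9.34-fold, SE 0.17), Nfkbiz (5.93-fold, SE 0.16) and Tnfaip3 (4.05-fold, SE 0.12). Of 36 interferon response genes 13 fell and 1 rose (16 and 2 adjusted over the list alone, camera adjusted p = 9.92e-06), including Cxcl10 (4.25-fold, SE 0.19), Irf1 (2.26-fold, SE 0.15) and Bst2 (2.13-fold, SE 0.17). Of 30 glycolysis and hypoxia genes 9 fell and 4 rose (12 and 6 adjusted over the list alone, camera adjusted p = 0.00863), with Vegfa 7.21-fold (SE 0.29), and the glucose transporters Slc2a3 2.58-fold (SE 0.17) and Slc2a1 1.84-fold (SE 0.13) lower. Of 43 oxidative phosphorylation genes 12 fell and 1 rose (14 and 1 adjusted over the list alone, camera adjusted p = 5.46e-06, and adjusted p = 0.0739 with an estimated correlation), including Cycs (log2 -1.12, SE 0.16), Ndufa4 (log2 -0.69, SE 0.10) and Sdhb (log2 -0.54, SE 0.11).

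Lists that rose covered oxidative stress, sterol synthesis, myeloid genes and surface receptors. Of 23 NRF2 and oxidative stress genes 13 rose and 1 fell (16 and 2 adjusted over the list alone, median log2 0.72, camera adjusted p = 2.14e-11), including, beside Hmox1, the glutathione synthesis genes Gclm (7.02-fold, SE 0.12) and Gclc (2.39-fold, SE 0.12) and the catalase gene Cat (2.61-fold, SE 0.12). Of 24 sterol synthesis genes 12 rose and none fell (15 adjusted over the list alone, median log2 0.49, camera adjusted p = 1.28e-09), including Msmo1 (4.62-fold, SE 0.23), Hmgcs1 (2.92-fold, SE 0.20), Fads2 (2.77-fold, SE 0.13) and Sqle (2.07-fold, SE 0.12). Of 24 myeloid genes 12 rose and 2 fell (14 and 2 adjusted over the list alone, median log2 0.61, camera adjusted p = 1.65e-06), including Csf1r, the macrophage growth factor receptor (4.73-fold, SE 0.17), Ccr2 (4.28-fold, SE 0.19), lysozyme Lyz2 (3.45-fold, SE 0.11) and Ly6c2 (2.86-fold, SE 0.16). Non-cultured replicates 4 and 5 had a lower mean of the myeloid list (6.54 and 6.40) than replicates 1 to 3 (7.03 to 7.12).

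Of 34 cytokine receptor and adhesion genes 14 rose and 6 fell (16 and 8 adjusted over the list alone, camera adjusted p = 0.00299), with Csf2rb2 14.0-fold (SE 0.18), Lifr 5.48-fold (SE 0.15), Cxcr4, the receptor for Cxcl12, 4.83-fold (SE 0.14) and Selplg 2.20-fold (SE 0.11) higher. Kit passed narrowly (log2 0.39, SE 0.12, limma adjusted p = 0.0429) and was called in 5 of the 15 fits that left out 1 array. Of 32 autophagy and FOXO genes 10 rose and 2 fell (11 and 3 adjusted over the list alone, camera adjusted p = 0.0059, and adjusted p = 0.0736 with an estimated correlation), including Ctsd (2.71-fold, SE 0.07), Gabarap (1.74-fold, SE 0.10) and Lamp2 (1.69-fold, SE 0.10).

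Genes of cell survival moved both ways. Of 28 pro-apoptotic genes 5 rose and 3 fell (7 and 4 adjusted over the list alone, camera adjusted p = 0.338): Dapk1 rose (log2 1.29, SE 0.18), while Tnfrsf10b (log2 -1.57, SE 0.17) and Bcl2l11 (log2 -1.08, SE 0.17) fell. Of 19 anti-apoptotic genes 3 rose and 3 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.399): Pim1 (log2 -1.80, SE 0.21) and Mcl1 (log2 -0.81, SE 0.14) fell, Naip2 (log2 1.13, SE 0.24) and Cflar (log2 0.77, SE 0.12) rose, and Bcl2 differed by log2 -0.02 (SE 0.13). Of 28 p53 target genes 6 rose and 6 fell (8 and 7 adjusted over the list alone, camera adjusted p = 0.756), with Trp53inp1 higher (log2 1.91, SE 0.22). Of 35 stem cell and early progenitor genes 9 rose and 5 fell (11 and 8 adjusted over the list alone, camera adjusted p = 0.548), with Sult1a1 (log2 2.19, SE 0.23) and Pdzk1ip1 (log2 1.48, SE 0.14) higher. Of 15 erythroid and megakaryocyte genes 3 rose and 1 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.0698), with Itga2b (log2 1.02, SE 0.14) and Gata1 (log2 0.70, SE 0.19) higher and Car1 (log2 -1.20, SE 0.33) lower. Car1 was called in 13 of the 15 fits that left out 1 array (adjusted p up to 0.0551) and not with only the 2 groups compared (adjusted p = 0.0569). Gata1 kept a similar fold but was not called with only non-cultured replicates 1 to 3 (log2 0.74, adjusted p = 0.0517) or 4 and 5 (log2 0.65, adjusted p = 0.205) as the reference. Of 20 lymphoid genes 2 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.197), with Siglech (log2 1.18, SE 0.23) and Flt3 (log2 0.63, SE 0.07) higher and Nkg7 (log2 -2.11, SE 0.20) lower.

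Culture and the interval since sorting were the same contrast in this design, so their effects cannot be separated. With only non-cultured replicates 4 and 5 as the reference, an alternative chosen after seeing the data, 1438 genes were called in place of 3022, and with only replicates 1 to 3 there were 2599.

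The third comparison, with EV against non-cultured, asks what culture changes when vesicles are present. Hmox1 rose 42.1-fold (log2 5.40, SE 0.23, n = 5 per group, limma adjusted p = 6.07e-10), Chil3 38.2-fold (SE 0.29), Fn1 16.1-fold (SE 0.25), Mmp8 15.9-fold (SE 0.23) and Pdk4 15.7-fold (SE 0.23). Kif1c (19.9-fold, SE 0.24) and Wasf3 (13.3-fold, SE 0.20) were among the 10 largest rises of genes that could be named here, with Chad (14.0-fold), Mterf1b (12.4-fold, not called with only non-cultured replicates 4 and 5 as the reference, adjusted p = 0.135) and Itgb3 (log2 3.58). Nr4a1 fell 41.8-fold (log2 -5.38, SE 0.11), Ptgs2 32.1-fold (SE 0.29), Fosb 21.7-fold (SE 0.14), Nr4a2 19.0-fold (SE 0.14), Egr1 18.0-fold (SE 0.21), Nr4a3 17.8-fold (SE 0.20), Plk2 15.1-fold (SE 0.17), Fos 13.3-fold (SE 0.26), Jun 12.6-fold (SE 0.25) and Dntt 10.3-fold (SE 0.25).

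In all, 1394 genes rose and 1741 fell (limma, adjusted p under 0.05), and 1691 and 1470 after quantile normalization. Of the 31 immediate early genes 30 fell (also 30 adjusted over the list alone), of the 33 DNA replication genes 29 fell (30 adjusted over the list alone; Mcm2 2.90-fold, SE 0.10), and of the 33 mitosis genes 23 fell and 1 rose (26 and 1 adjusted over the list alone; Top2a 3.67-fold lower, SE 0.14, and Mki67 1.99-fold lower, SE 0.15). Of 23 NRF2 genes 14 rose and 1 fell (16 and 1 adjusted over the list alone), with Gclm 6.40-fold higher (SE 0.12). Of 24 sterol genes 12 rose (14 adjusted over the list alone), with Msmo1 3.47-fold (SE 0.23) and Hmgcs1 2.93-fold (SE 0.20) higher. Of 24 myeloid genes 10 rose and 1 fell (13 and 3 adjusted over the list alone, camera adjusted p = 4.34e-05, and adjusted p = 0.0549 with an estimated correlation), with Csf1r 5.21-fold (SE 0.17) and Lyz2 3.55-fold (SE 0.11) higher.

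Of the 34 stromal and mesenchymal genes 6 rose and none fell, also when adjusted over the list alone (median log2 0.14, camera adjusted p = 0.0059, and adjusted p = 0.208 with an estimated correlation). Beside Fn1 these included Cald1 (log2 0.69, SE 0.09), Cxcl12 (log2 0.48, SE 0.13, limma adjusted p = 0.0233, not called without non-cultured replicate 4 at adjusted p = 0.0617) and Col1a2 (log2 0.31, SE 0.09, limma adjusted p = 0.0231, called in 12 of the 15 fits that left out 1 array). Dlk1 did not pass (log2 0.13, SE 0.13). Csf2rb2 rose 10.4-fold (SE 0.18), and the cytokine receptor and adhesion list was called (camera adjusted p = 0.0281, and adjusted p = 0.0739 with an estimated correlation). Kit did not pass (log2 0.26, SE 0.12, limma adjusted p = 0.196). The stem cell genes moved both ways, with Pdzk1ip1 higher (log2 1.26, SE 0.14) and Angpt1 lower (log2 -2.11, SE 0.22). Pim1 (log2 -1.74, SE 0.21) and Mcl1 (log2 -0.96, SE 0.14) fell, and Bmf, a pro-apoptotic gene, rose (log2 0.97, SE 0.21). A fold of at least 1.5 left 893 genes higher and 1173 lower, and with only non-cultured replicates 4 and 5 as the reference 1369 genes were called, against 2698 with only replicates 1 to 3.

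The comparisons of both cultured groups with non-cultured cells shared 995 genes that rose and 1231 that fell, and 3 genes went opposite ways. Independent lists of these sizes would share 94.1 and 119.7 genes. The 20 simulations held no change in any group and shared 0 on average, so they do not show how far the shared non-cultured arrays add to the overlap. With the non-cultured arrays split between the comparisons, 403.8 and 521.4 genes were shared on average over 5 splits. These fits had fewer non-cultured arrays and called only 1789 genes without EV and 1657 with EV on average, against 3022 and 3135. The drop in shared genes therefore does not measure what the shared arrays add. Across genes, which are not independent replicates, the fold changes of both comparisons correlated at r = 0.896 (0.770 with the non-cultured arrays split) with a covariance of 0.177, against 0.0152 simulated from the shared arrays alone.

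A culture score asked whether vesicles shift cells along the culture response. It is the mean log2 signal of the 100 genes with the largest rise minus that of the 100 with the largest fall, in both cultured groups together against non-cultured cells. The score was -2.57 ± 0.07 (SD, n = 5) in non-cultured cells, 2.38 ± 0.09 without EV and 2.35 ± 0.07 with EV. The difference with EV against without EV was log2 -0.03, within the spread between replicates (two-sided exact permutation test, p = 0.619, with 0.00794 the smallest p that these group sizes allow). The difference depended on which genes the score held: it was log2 -0.17 with 50 genes each way (exact permutation p = 0.0714) and log2 0.17 with all probe sets (exact permutation p = 0.0397), of which 6 were called higher with EV. Of the 100 rising genes, 3 were themselves called higher with EV. Leaving out what was called with EV, an alternative chosen after seeing the data that lowers the difference by construction, gave log2 -0.15 with genes and -0.16 with all probe sets.

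**Figure D4:**
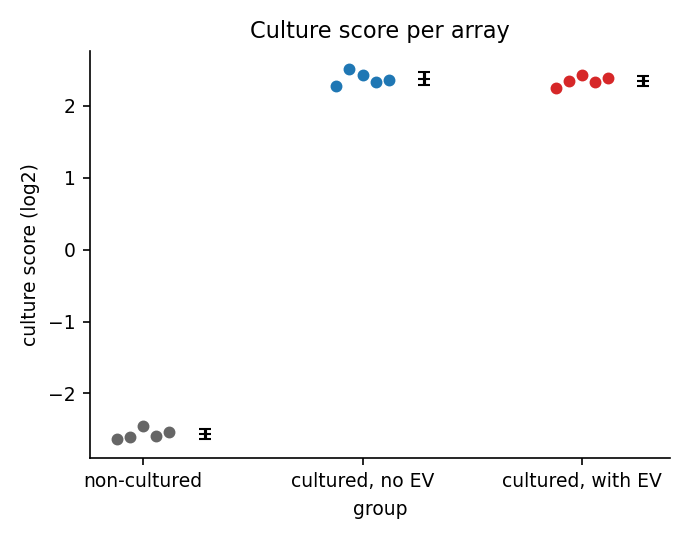
Culture score per array in log2 units, with 1 point per array in each of the 3 groups and the mean with SD (n = 5) beside them. The non-cultured arrays lie between -2.64 and -2.46, and the arrays with EV (2.25 to 2.44) overlap those without EV (2.28 to 2.51).

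Gene by gene, the change with EV showed no clear relation to the change with culture. Only 44 genes were called with EV, so error may make up much of these fold changes and draw r toward 0. A small r therefore does not exclude a relation. Across 22180 genes the log2 fold change with EV against without EV and that of both cultured groups against non-cultured cells had r = 0.0105 and a covariance of 0.000928. The jackknife standard error of this r, pooled over the arrays of all 3 groups, was 0.0713. It includes a shift that depends on the group of the array left out. Thus r was 0.0246 to 0.0441 without 1 array with EV and -0.0199 to 0.00157 without 1 array without EV. In 100 simulations r lay between -0.044 and 0.0316. They held neither an EV nor a culture effect and took genes as independent, so this is not the chance range for these data. In the form that uses the arrays without EV on both sides, r was -0.219 with a covariance of -0.0197. The same simulations, again without a culture effect, gave -0.5 and -0.0152. With the arrays without EV split, r was -0.0511.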

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

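The test of whether the array with EV of replicate 1 alone accounts for the genes higher with EV was chosen after the result was seen. For the other tests, what each explanation would give was written down before its value was computed, although the patterns themselves had been seen.

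The 40 genes higher with EV had a median rise of log2 1.29 (95% bootstrap interval 0.994 to 1.71). The 34 stromal and mesenchymal genes had an upper 95% bound of 0.14 for their median and none exceeded log2 1, but Cald1 (log2 0.68, limma adjusted p = 0.00128) rose, while Sparc (0.38), Col1a1 (0.32), Col1a2 (0.10) and Col3a1 (-0.02) did not pass. Because the profile of AFT cells was not analysed here and the list is a generic one, stromal cells or RNA carried over with the vesicles, transcripts delivered by them and transcripts switched on in their presence cannot be told apart, and the genes' level without EV, at a median percentile of 56.4 with 12 of the 40 below the 40th, does not decide it. Without the array with EV of replicate 1, 34 of the 40 genes stayed called, and its part in the other 6 stays open. Leaving out another single array kept 29 to 39 of the 40, so a loss of this size is not particular to that array. Chance is unlikely to account for the count, since none of the 99 other splits drawn of the 10 arrays called as many genes, with 44 genes against at most 4. The result, 1 of 100 with the real split, is the smallest this test can give. The other splits mix arrays of both groups, so real differences widen their spread.

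The immediate early genes were lower after culture by a median of log2 -2.11, and handling of the cells up to RNA extraction straight after sorting may have raised them in the non-cultured samples. Of the heat-inducible genes Hspa1a, Hspa1b and Dnajb1, 2 were also lower after culture (log2 -0.50 for Hspa1b and -0.58 for Dnajb1), while Hspa1a (log2 -0.30, limma adjusted p = 0.208) did not pass. In non-cultured cells Hspa1a (mean log2 signal 3.85) and Hspa1b (4.29) lay below the median of every array. Their changes cannot be told from background, and Dnajb1 alone lay higher (6.04). Sort handling and an effect of culture on stimulated cells cannot be told apart, because every non-cultured sample was taken straight after the sort. Chance is also unlikely to account for both counts against non-cultured cells (1 of 100 splits each): 3022 genes without EV against at most 1 in other splits, and 3135 with EV against at most 64.

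The array with EV of replicate 1 stood apart, with a mean correlation of 0.9642 with its group against 0.9735 to 0.9764 for the others. A share of cells of another lineage large enough to raise a list by 0.5 was argued against, since the myeloid, lymphoid, erythroid and megakaryocyte and stromal lists had a highest upper 95% bound of 0.295 for their median deviation. A candidate explanation is a weaker signal or poorer RNA on that array: across genes, its deviation fell with brightness (r = -0.35), whereas the other 4 arrays with EV had r between -0.0224 and 0.169. A smaller share stays open, and no other biological explanation was tested.

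A single array lay far from the others of its group in 30 of 465 groups of 5 values tested, where chance gives about 1 in 20 (23.25). Of these, 8 were the array with EV of replicate 1: beside its correlation, it had the lowest Kit (log2 signal 9.517, others 9.892 to 10.03), Dntt (5.491, others from 6.648), Aurkb (5.882, others from 6.313), Bcl2l11 (5.502, others from 5.991) and Car1 (3.702, others from 4.132), and the highest Odc1 (7.382, others up to 7.195) and Rplp0 (8.903, others up to 8.616).

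Among the other arrays with EV, Dusp6 was low in replicate 2 (8.106), and Cenpf (7.594) and Vegfa (7.427) were high in replicate 3. Among arrays without EV, replicate 1 had the lowest mean level of MYC target and ribosome biogenesis genes (7.295, others from 7.493), of anti-apoptotic genes (6.556, others from 6.671) and of glycolysis and hypoxia genes (6.702, others from 6.812), and the lowest Cenpf (5.638) and Sult1a1 (7.102). Replicate 4 without EV had a high Dlk1 (4.789), Car1 (5.048) and Hspa9 (9.093) and a low Mterf1b (6.861), and replicate 5 had a high Cald1 (4.494) and Plk2 (4.484).

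Among non-cultured arrays, replicate 1 had the highest mean level of DNA replication genes (7.347, others up to 7.234) and of cytokine receptor and adhesion genes (6.776, others up to 6.65). Replicate 3 had a high Pdk4 (5.239) and a low Gclm (6.963), replicate 4 a low Cxcl12 (4.314) and Cxcl10 (5.573), and replicate 5 a low Ddr2 (3.42) and a high Ptn (6.173).

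Probe sets without a single gene symbol, outside the comparisons of genes, also differed with EV. Of 17824 such probe sets, 17 were called (limma over all probe sets), 16 higher and 1 lower. Some of the higher ones had identical fold changes, SEs and means and are not separate measurements: 17548358 and 17548692 (log2 1.85), and 17548311, 17548313, 17548642 and 17548644 (log2 1.797). Probe set 17549126 was higher with EV by log2 8.983, with a mean of 12.15 ± 0.12 (SD, n = 5) against 3.17 ± 0.11 without EV. In the non-cultured arrays it ranged from 2.81 to 10.14. Probe set 17549150 was higher by log2 6.636, at 11.27 ± 0.35 against 4.63 ± 0.35.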

How the results depend on the processing

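The alternatives that leave out several non-cultured arrays, or the genes called with EV from the culture score, were chosen after seeing the data. Leaving out each array in turn gave 29 to 53 genes for EV against without EV, 2526 to 3332 for without EV against non-cultured and 2604 to 3177 for with EV against non-cultured. The 29, 1.5 times below 44, came without replicate 2 of the group without EV. It gave a culture score difference of log2 -0.06 to 0.03 (exact permutation p = 0.143 to 0.992), a correlation of EV and culture effects of -0.0199 to 0.0441, and 35 to 40 called list tests against 39. The culture score difference was log2 -0.174 (exact permutation p = 0.0714) with 50 genes each way. It was log2 -0.146 without genes called with EV, lower by construction since the 3 genes left out were all higher with EV. It was 0.165 (exact permutation p = 0.0397) with all probe sets, where 6 of the 100 rising probe sets were called with EV and leaving those out gave -0.162, again lower by construction. A fold of at least 1.5 left 2066 of 3135 genes for with EV against non-cultured, by construction. Without non-cultured replicates 1, 2 and 3, a fit with fewer samples, 1438 and 1369 genes were called against non-cultured cells, and without replicates 4 and 5 there were 2599 and 2698. With only replicates 4 and 5 as the reference, several named genes lost their calls without EV. Among them were Mcl1 (log2 -0.59, limma adjusted p = 0.0973), Siglech (log2 0.92, limma adjusted p = 0.124) and Rplp0 (log2 -0.85, limma adjusted p = 0.0937). Rpsa (log2 -0.34, limma adjusted p = 0.114), Kit (log2 0.16, limma adjusted p = 0.676) and the stromal list member Mmp2 (log2 0.83, limma adjusted p = 0.0702) also lost theirs. So did Mterf1b (limma adjusted p = 0.11) and Gata1 (limma adjusted p = 0.205). With EV, calls were lost for Bmf (log2 1.04, limma adjusted p = 0.055), Col1a2 (log2 0.27, limma adjusted p = 0.216), Cxcl12 (log2 0.56, limma adjusted p = 0.126) and Mterf1b (limma adjusted p = 0.135). The folds of these genes kept their sign in this smaller fit. With only replicates 1 to 3, Myc was called without EV (log2 0.73, limma adjusted p = 0.00238), Kit with EV (log2 0.41, limma adjusted p = 0.0455), and Car1 was not called without EV (log2 -0.83, limma adjusted p = 0.0853). Gata1 was also not called without EV there (log2 0.74, limma adjusted p = 0.0517). Nor were Col1a2 (log2 0.33, limma adjusted p = 0.0532) and Cxcl12 (log2 0.43, limma adjusted p = 0.108) with EV.

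The replicate numbers showed little pairing of the arrays across all genes: 1 of 15 correlations between same-numbered arrays was over 0.1, and 3 of 15 were the best match. A source shared by replicate number is not excluded by this, since replicates 4 and 5 had the lowest myeloid list means in all 3 groups. With the replicate number as a block (a paired fit) 39, 2987 and 3063 genes were called, with 32 of the 44 genes called with EV kept and 37 list tests called, while the culture score difference and the correlation cannot change with a balanced block. Quantile normalization gave 43, 3049 and 3161 genes and kept 42 of the 44. It turned the balance against non-cultured cells, to 1650 higher and 1399 lower without EV and to 1691 higher and 1470 lower with EV, and the cause was not tested. Beyond these summaries, named genes kept their outcome, called or not called, in 4400 tests under alternatives, lost a call in 84 and gained one in 10, and lists kept theirs in 1739, lost a call in 45 and gained one in 16. Of values not called either way, 40 changed sign. Signal over background is not given, so how far dim genes are limited by it is unknown, and 13308 genes remained without the dimmest 40%.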

Other observations

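The non-cultured arrays held a difference that no group explains, and part of it ran by replicate number in all 3 groups. Replicates 4 and 5 had lower levels of some myeloid granule genes than replicates 1 to 3, but not of lysozyme Lyz2 (log2 signal 9.69 and 9.65 against 9.42 to 9.68). Elane, neutrophil elastase, had a log2 signal of 8.30 and 7.86 in replicates 4 and 5 and 8.88 to 9.01 in the others, and Ctsg, cathepsin G, 8.48 and 8.27 against 8.91 to 9.30. Ms4a3 had 6.27 and 6.14 against 6.70 to 7.46. The mean of the stem cell and early progenitor list was higher in replicates 4 and 5 (7.16 to 7.20) than in replicates 1 to 3 (6.92 to 6.95), and Mecom, a stem cell transcription factor gene, had 7.45 and 7.35 against 6.84 to 7.15. Some other list means separated and some overlapped. Integrated stress genes were lower in replicates 4 and 5 (7.10 to 7.13 against 7.30 to 7.40) and NF-kB genes higher (6.94 to 7.04 against 6.745 to 6.789). The myeloid list mean was also lowest in replicates 4 and 5 without EV (7.61 and 7.44, others from 7.65) and with EV (7.46 and 7.55, others from 7.60). The stem cell list did not separate this way in the cultured groups. These genes and lists were chosen after their values were seen, and 2 arrays against 3 were not compared by a test.

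The cultured arrays did not share 1 direction within the myeloid list. Csf1r and Lyz2 were higher after culture in both cultured groups, whereas Mpo, myeloperoxidase, had a mean log2 signal of 9.67 without EV and 9.74 with EV against 10.08 to 10.53 in the non-cultured arrays.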
